A study of Homo sapiens with 2 samples.

How the data were processed

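Gene expression was measured on Affymetrix U133 oligonucleotide arrays in B lymphocytes purified from human peripheral blood and left unstimulated. RNA was extracted with Trizol and labelled with biotin, per the labels' protocols. The study design also names cells stimulated through the B cell receptor with anti-IgM, and those are not analysed here. The 2 arrays used here are the biological replicates of the resting group, numbered as in the labels. The labels do not say whether they came from different donors. With 1 group of 2 arrays, no test between groups could be made and no p-value is given.

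Per the submitters' processing notes, the authors computed the signals with MAS5, the Affymetrix algorithm that condenses each probe set into 1 signal. Its version, scaling target and masks are not given in the sources used here. The deposited values are on the log2 scale. The base was checked on the values, since 100.0% of the low signals (log2 under 3) were multiples of 0.1 on the linear scale within 0.02 units on each array. The linear signals had a 2% trimmed mean of 499.9 on both arrays, so both had been scaled to the same target. The column medians were 6.38 for replicate 1 and 6.49 for replicate 2. Values ran from -3.32 to 15.31 on replicate 1 and from -2.32 to 15.56 on replicate 2. Detection calls were not used here. MAS5 subtracts mismatch signal, so its log2 values scatter widely when the signal is low.

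The table held 54675 probe sets, of which 62 Affymetrix control probe sets were left out. Probe sets were named through the platform annotation, with symbols updated through the gene identifier from the RefSeq table of GRCh38.p14 for 41037 of the 41091 probe sets with 1 gene symbol. Another 1801 probe sets had several symbols and 11721 are not named here, and neither kind was used for a gene. A further 184 probe sets were left out for the donors' privacy or because they report genotype or clonal rearrangement. These were Y-linked and X-inactivation genes, variable segments of antigen receptors, KIR genes and other genes whose signal depends on a common deletion or allele. The remaining 19678 genes were each represented by the probe set with the highest mean signal. Probe sets whose identifiers carry an x or s can hybridise to related transcripts, and their values are less certain. HSPA1A has only probe sets with several symbols, and some items are not reported here. Signals of different probe sets are not compared with each other, since probe affinity differs.

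The background cutoff was the 95th percentile, per array, of 95 probe sets of 49 tissue-restricted genes (such as those of liver, pancreas, pituitary, lens, heart, kidney, lung, thyroid, testis, skin, brain and gut). It lay at 8.09 on replicate 1 and 8.13 on replicate 2 on the log2 scale, or 272.4 and 279.8 signal units. A gene was called measured when its mean log2 signal exceeded the mean of the 2 cutoffs, and above background on an array when it exceeded that array's cutoff. Differences are replicate 2 minus replicate 1, centred on the median of measured genes, which was -0.036 before centring.

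The 26 gene lists, the rule for named genes and the main settings were fixed before the data were examined. The values turned out to be log2 already, so the signal floors foreseen for linear values were not part of the main setting and were run afterwards. Named genes were 46 symbols listed in advance, of which 43 had a probe set with that gene alone. To these were added the 10 genes with the largest difference in each direction among measured genes above background on both arrays whose measured probe sets all differed the same way. In each list outside its random band, the 3 members with the largest difference in the list's direction were also named. Other list members named as examples were chosen after their values were seen. For each list with at least 5 measured genes, the median difference was placed among 10000 random lists of the same size matched on mean signal in 20 bins. A list was called outside the band below the 2.5th or above the 97.5th percentile. These percentiles describe the 2 arrays and are not p-values, because genes are not replicates. Differences of 2 probe sets of the same gene were correlated and set against 1000 random pairings within signal bins. Another 6 gene lists were chosen after the data had been seen and are used only in the additional observations.

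The list procedure was tested on random lists drawn from all measured genes, with their real differences. Of 100 random lists of 15 genes with no added shift, 4 fell outside the band, and 75 of 100 did with an added shift of 0.15 log2. With 56 genes the numbers were 6 and 100. These lists were not drawn from the brightest genes, so the rates do not cover a very bright list such as the ribosomal proteins. Simulated differences with a gene-level SD of 0.5 times the probe set noise gave a correlation of 0.194 between probe sets against an expected 0.2 over 3631 genes. Alternatives covered quantile normalization, no centring, signal floors of 16 and 64, a started log, cutoffs at the 90th and 99th percentile, no cutoff, the median over a gene's probe sets, probe sets without an x, the reference list without KRT10, matching on the 100 nearest genes and each array alone. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used. Array number, at 2, limits the precision of every value.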

Results

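Resting B cells, the antibody-forming lineage of lymphocytes, were profiled on 2 arrays that served as the unstimulated baseline of a study of acute B cell receptor stimulation. The questions open to these arrays were which gene groups gave signal in resting cells and how closely the biological replicates matched. Of 19678 genes, 8583 (43.6%) were measured above background and 8387 were above background on both arrays. All levels are log2 MAS5 signals, as mean ± SD of the 2 arrays. The 3′ to 5′ signal ratio of the GAPDH control probe sets, a check of RNA integrity, was 1.43 on replicate 1 and 1.35 on replicate 2. For ACTB it was 2.27 and 1.87. The GAPDH gene itself gave 14.03 ± 0.01 (SD, n = 2) and ACTB gave 15.16 ± 0.17 (SD, n = 2).

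B cell genes were detected throughout. All 19 lineage genes with a probe set were above background on both arrays. MS4A1, which encodes CD20, gave 14.74 ± 0.19 (SD, n = 2). CD79A and CD79B, the signalling chains of the B cell receptor, gave 14.52 ± 0.21 and 13.64 ± 0.14. The inhibitory coreceptor CD22 gave 13.46 ± 0.00 and the lineage transcription factor PAX5 gave 13.03 ± 0.02. All 18 genes of B cell receptor signalling were above background, among them the kinases SYK (12.64 ± 0.06) and BTK (12.02 ± 0.10) and the phospholipase PLCG2 (12.96 ± 0.03). The 14 MHC class II presentation genes were also all above background. HLA-DRA gave 15.11 ± 0.20, the invariant chain CD74 gave 15.25 ± 0.17, and the class II transactivator CIITA gave 11.30 ± 0.12.

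**Figure D1:**
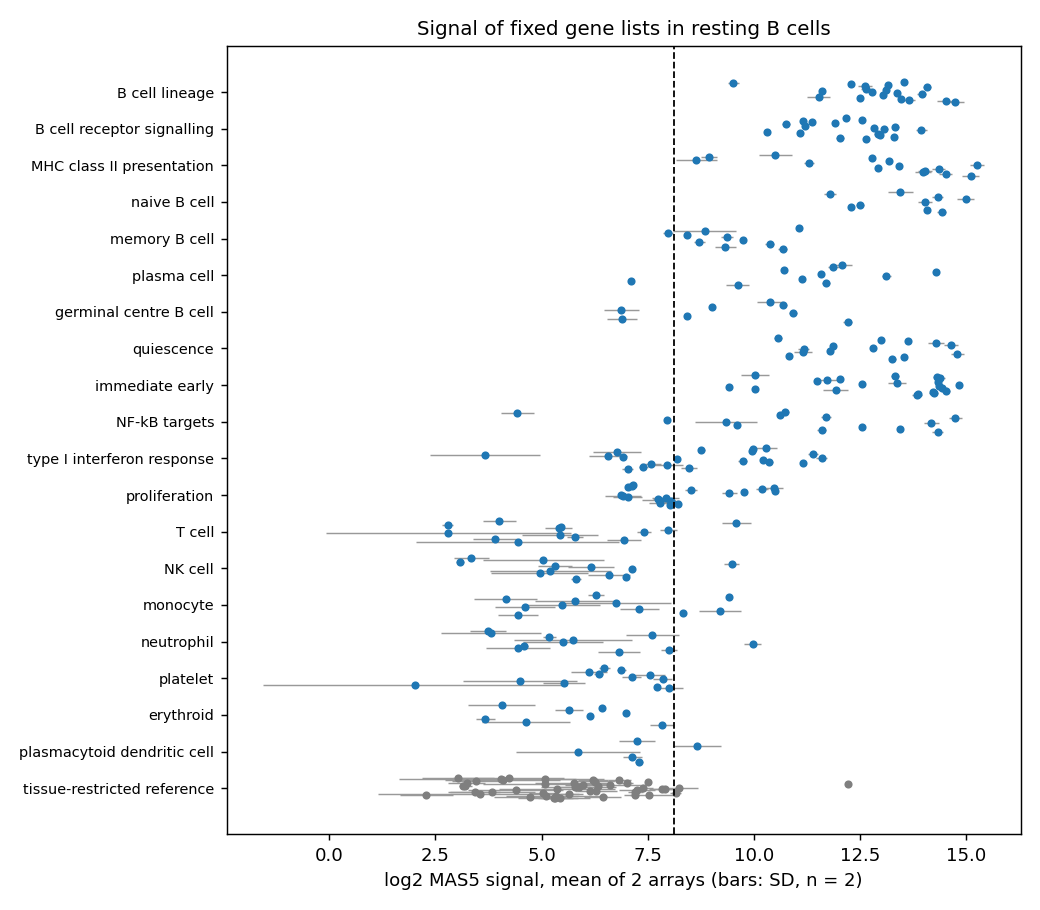
Mean log2 MAS5 signal of each gene (points, 1 per gene) with its SD over the 2 resting arrays (bars) in fixed gene lists, and the mean background cutoff (dashed line). All 19 B cell lineage genes and all 21 immediate early genes lie to the right of the cutoff, while 7 of 72 markers of other blood cells are above background on both arrays.

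Genes of several B cell stages gave signal. All 9 naive B cell genes were above background, including TCL1A, a coactivator of AKT, at 14.42 ± 0.11 (SD, n = 2), IL4R at 14.08 ± 0.02 and the constant region gene IGHD at 14.02 ± 0.17. In the memory list, 9 of 10 genes were above background on both arrays. CD27 gave 10.68 ± 0.11 and COCH gave 11.05 ± 0.05, whereas IGHG1 was not well above background. In the plasma cell list, 9 of 10 genes were above background. JCHAIN, the joining chain of secreted antibody, gave 14.29 ± 0.04, XBP1 gave 11.69 ± 0.10 and PRDM1 gave 9.61 ± 0.27. SDC1, the plasma cell surface marker, was not well above background at 7.11 ± 0.03. In the germinal centre list, 6 of 8 genes were above background, with BCL6 at 12.21 ± 0.11. MME and RGS13 were not well above background. At the 99th percentile cutoff, 0 memory, 5 plasma cell and 1 germinal centre genes were above background, and with the median over probe sets 3 germinal centre genes were. Here and below, the 99th percentile cutoff falls on probe sets of KRT10, a reference gene that itself gave clear signal.

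Genes of quiescence and of acute activation were detected side by side. All 14 quiescence genes were above background, with KLF2 at 13.26 ± 0.08 (SD, n = 2), TXNIP at 14.64 ± 0.17 and FOXO1 at 11.78 ± 0.03. All 21 immediate early genes, the class that responds first to receptor stimulation, were also above background on both arrays. FOS gave 13.84 ± 0.12, JUN 14.24 ± 0.11 and JUNB 14.22 ± 0.06. EGR1 gave 11.92 ± 0.29, NR4A1 13.37 ± 0.22 and NR4A2 14.34 ± 0.04. The phosphatase gene DUSP1 gave 14.82 ± 0.06, the early activation antigen CD69 gave 14.31 ± 0.09 and MYC gave 11.72 ± 0.23. The median of the 21 genes was 5.67 log2 units above the cutoff on replicate 1 and 5.76 on replicate 2. Of 13 NF-kB target genes, 11 were above background, including NFKBIA (14.33 ± 0.12), CD83 (14.74 ± 0.16) and TNFAIP3 (13.44 ± 0.02). TRAF1 and EBI3 were not well above background. The NF-kB count was 5 at the 99th percentile cutoff. All 10 heat shock genes were above background, among them DNAJB1 (14.71 ± 0.21), BAG3 (13.51 ± 0.05) and HSPA6 (13.94 ± 0.08), whose probe sequences may be shared with close relatives. HSPA1A is not reported because its probe sets carry several gene symbols.

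Proliferation genes gave a split picture. Of 20 genes, 7 were above background on both arrays, 3 on a single array and 10 on neither. The 7 were TOP2A, which gave 8.22 ± 0.05 (SD, n = 2) close to the cutoff, and the DNA replication genes TYMS, RRM2, MCM2, MCM4, MCM6 and PCNA, with MCM2 at 10.50 ± 0.04 and PCNA at 10.47 ± 0.22. The count was 14 without probe sets whose identifiers carry an x, 3 with the median over probe sets and 0 at the 99th percentile cutoff. Dropping x probe sets cannot make a gene brighter. Measured genes rose to 9360 in that setting, so its background cutoff was lower. MKI67, at 8.02 ± 0.08, and the mitotic genes CDK1, AURKA, AURKB, PLK1 and BIRC5 were not well above background. Of 20 type I interferon response genes, 12 were above background on both arrays. MX1 gave 11.15 ± 0.01 and ISG15 gave 11.59 ± 0.13, while IFI44L (7.57 ± 0.23), IFIT1 and RSAD2 were not well above background. The interferon count was 0 at the 99th percentile cutoff.

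Housekeeping and trafficking groups were mostly detected. In the homing list, 12 of 14 genes were above background, including CXCR4 (14.98 ± 0.20, SD, n = 2), CXCR5 (12.83 ± 0.07) and CCR7 (12.42 ± 0.12), and CXCR3 and CCR10 were not. All 15 apoptosis and survival genes were above background, with MCL1 at 14.03 ± 0.02 and BCL2 at 11.21 ± 0.05. For glycolysis and hypoxia the number was 15 of 18, for ribosomal proteins 56 of 59 and for nuclear oxidative phosphorylation genes 64 of 65. At the 99th percentile cutoff the counts were 7 for homing, 6 for apoptosis and survival and 7 for glycolysis and hypoxia, and with the median over probe sets 8 apoptosis and survival genes were above background.

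Markers of other blood cells were largely at background. Over 7 lists, 7 of 72 markers with a probe set were above background on both arrays. The total was 12 at the 90th percentile cutoff, 10 without x probe sets and 10 with the reference list without KRT10. It was 3 with the median over probe sets and 0 at the 99th percentile cutoff. At the 95th percentile cutoff these were CD6 (9.58 ± 0.34, SD, n = 2) among 13 T cell genes, KLRB1 (9.47 ± 0.18) among 12 NK cell genes, LYZ (8.34 ± 0.02), S100A8 (9.20 ± 0.49) and MNDA (9.41 ± 0.02) among 11 monocyte genes, MMP9 (9.97 ± 0.21) among 11 neutrophil genes and PTCRA (8.66 ± 0.57) among 5 plasmacytoid dendritic cell genes. CD6 and MNDA are also known in B cell subsets. The T cell receptor complex genes CD3D (2.74 and 6.12 on the 2 arrays) and CD3E (6.65 and 7.22) were not well above background. Neither were the cytotoxic granule genes NKG7 (5.76 and 4.15) and GNLY (6.21 and 4.19), or the monocyte genes CD14 (4.12 and 4.79) and S100A9 (6.98 and 7.63). No platelet or erythroid gene was above background on both arrays, with PPBP at 7.99 ± 0.34, PF4 at 7.72 ± 0.01 and HBB at 7.83 ± 0.29. In the tissue-restricted reference list, KRT10 was the single gene of 49 above background on both arrays, at 12.21 ± 0.07. That count was 4 at the 90th percentile cutoff, 3 without x probe sets, 2 with the cutoff set without KRT10, 2 on replicate 1 alone and 3 on replicate 2 alone. A low count in this list was fixed in advance, since its own probe sets set the cutoff.

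The replicates matched closely. Across the 8583 measured genes, which are not independent replicates, Pearson's r was 0.988 and Spearman's rho 0.985. The difference between arrays had an SD of 0.237 log2, or 1.18-fold, and 97.3% of measured genes lay within 1.5-fold. With measured genes split by signal into 4 groups of equal size, the SD was 0.310 in the dimmest group and 0.163 in the brightest. There were 21 measured genes over 2-fold higher in replicate 2 and 10 over 2-fold lower. Without x probe sets, where the cutoff was lower, the counts were 45 and 13. They were 37 and 7 with the median over probe sets, 0 and 0 at the 99th percentile cutoff, and 1887 and 1596 with no cutoff. Over all probe sets, most of them below background, Pearson's r was 0.931.

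**Figure D2:**
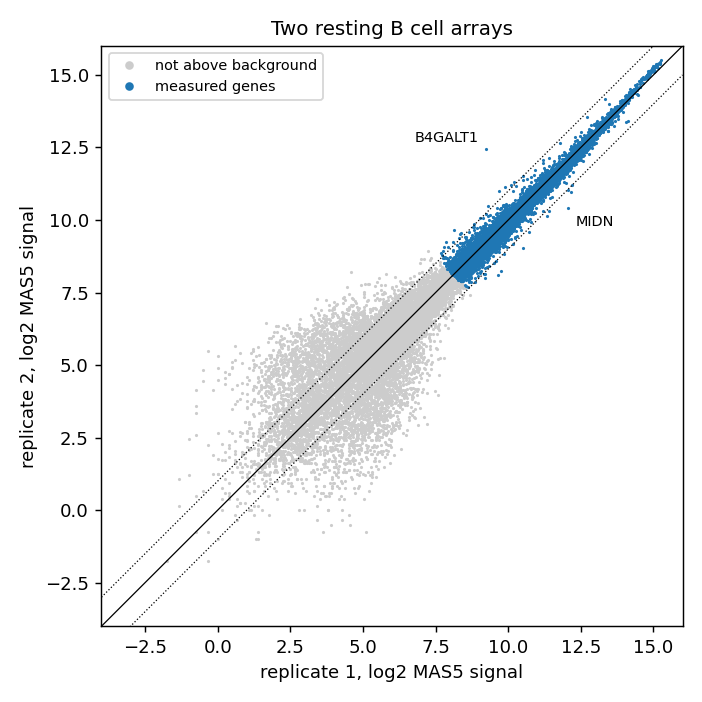
Log2 MAS5 signal of each gene on replicate 1 (x axis) and replicate 2 (y axis), for measured genes (blue) and others (grey), with the line of equality (solid) and lines of 2-fold difference (dotted). The 8583 measured genes follow the line with an SD of 0.237 log2, and among them B4GALT1 and MIDN have the largest difference in each direction.

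Among measured genes, the largest difference was in B4GALT1, a galactosyltransferase, at 9.24 on replicate 1 and 12.43 on replicate 2, a centred difference of 3.23 log2. Its other measured probe set differed by 0.17. EIF5A, a translation factor, was higher in replicate 2 by 1.20 log2, and its other measured probe sets also differed, by 1.07 and 2.11. EHBP1L1 was higher by 1.29, with 0.62 and 0.82 at its other measured probe sets. GRK2, a receptor kinase, was higher by 1.35 and SH3GLB2 by 1.23, while their other measured probe sets differed by 0.31 and 0.40. The remaining genes named on the higher side, TBC1D8B, PSENEN, SMG1P5, CLCN7 and the kinase gene PIM2, differed by 1.14 to 1.55 and had 1 measured probe set each. On the lower side, the difference was -1.61 for MIDN, -1.48 for FAM221A and -1.18 for POLR2A, the largest subunit of RNA polymerase II. CARMIL1, NAF1, BBIP1, KANSL1L, PPP3CB-AS1, ATP13A3 and EME2 had differences between -1.04 and -0.94. Other measured probe sets differed far less, by -0.005 for CARMIL1, -0.055 and -0.165 for BBIP1 and -0.214 for KANSL1L. The rest of the genes named on the lower side had 1 measured probe set each. Of the 31 genes over 2-fold, 11 had several measured probe sets. In 7 of these all measured probe sets pointed the same way, and in 1 all were over 2-fold. With the median over all probe sets of a gene, the sign was turned for MIDN (1.48), CARMIL1 (0.82), BBIP1 (0.38) and ATP13A3 (0.26), and the difference of B4GALT1 was 0.11. These medians take in probe sets below background, whose log differences are imprecise. The difference was also closer to 0 for TBC1D8B (0.63), GRK2 (0.34), EHBP1L1 (0.68), SH3GLB2 (0.49), KANSL1L (-0.43) and EME2 (-0.20). With 1 array on each side, none of these differences has a replicate check.

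Between the replicates, 1 of the 18 gene lists with enough measured genes lay outside the band of random lists, where chance alone puts about 5% of lists. Ribosomal protein genes were higher in replicate 2, in 53 of 56 members, by a median of 0.25 log2 (1.19-fold), above all 10000 random lists (band 0.07 to 0.16). RPS27 was higher by 0.36, RPL39 by 0.35 and RPS21 by 0.34. Other genes of equal brightness were shifted as much. Between log2 signals of 14.5 and 15, the median difference was 0.24 for 19 ribosomal protein genes and 0.25 for 31 others, and above 15 it was 0.26 for 27 and 0.26 for 14. Under quantile normalization the list's median was 0.05, at the 94.5th percentile. MHC class II presentation genes lay just inside the band with a median of 0.17 (97.3rd percentile). Of its 14 members, 11 were higher in replicate 2, such as HLA-DRA (0.31) and CD74 (0.28), both above a signal of 15, and 3 were lower, LGMN (-0.64), RFXANK (-0.52) and RFXAP (-0.21). The naive B cell list had a median of 0.19 (95.5th percentile), the immediate early list 0.14 (93.7th) and the memory list 0.11 (92.6th). B cell lineage (0.11, 91.0th), NF-kB targets (0.12, 92.1st), heat shock (0.16, 74.1st) and B cell receptor signalling (0.02, 50.2nd) also lay inside, as did quiescence (0.00, 13.4th), plasma cell (-0.06, 15.97th), germinal centre (-0.01, 47.7th), proliferation (-0.03, 44.8th) and type I interferon response (-0.05, 31.4th). Glycolysis and hypoxia (0.00, 33.4th), apoptosis (0.04, 64.4th), homing (0.04, 75.0th) and oxidative phosphorylation (0.04, 77.0th) completed the set.

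**Figure D3:**
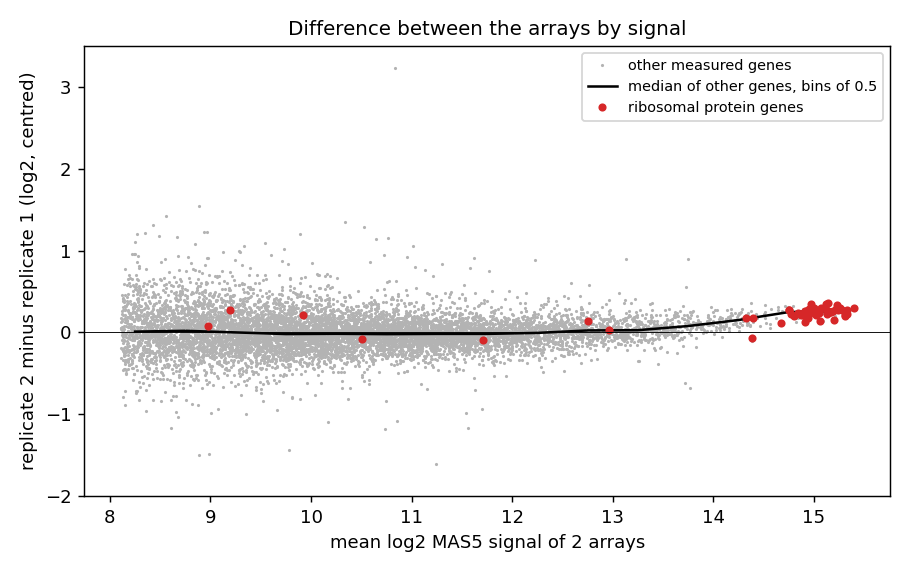
Centred log2 difference, replicate 2 minus replicate 1 (y axis), against mean log2 MAS5 signal (x axis) for measured genes, with ribosomal protein genes in red and the median of all other genes in bins of 0.5 as a line. The line rises at the bright end, and the 27 ribosomal protein genes above a signal of 15 have the same median, 0.26, as the 14 other genes there.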

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

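Signal was also present in probe sets that stand for no gene above. Of 11721 probe sets not named here, 1712 (14.6%) were above background on both arrays, and of 1801 probe sets with several gene symbols, 809 (44.9%) were. Among the 40907 probe sets used, the share was 33.8%. These stand here because they are signal in probe sets that no gene or gene list used. No explanation for them was tested.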

How the results depend on the processing

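The settings with signal floors, with a started log, without x probe sets, without KRT10 and with matching on the 100 nearest genes were chosen after seeing the data. With no cutoff, the SD of the difference was 0.929, rho 0.961 and r 0.954, with 1887 genes over 2-fold higher and 1596 lower in replicate 2, by construction, since genes below background then enter. The 99th percentile cutoff falls on KRT10 probe sets and left 1995 measured genes, with rho 0.974, 0 genes over 2-fold higher and 0 lower, and 0 T cell, 0 NK cell, 0 monocyte, 0 neutrophil, 0 plasmacytoid dendritic cell, 0 proliferation, 0 memory B cell and 0 interferon response genes detected, with 1 germinal centre, 5 plasma cell, 5 NF-kB, 6 apoptosis, 7 glycolysis and 7 homing genes. The median over probe sets gave rho 0.971, 37 genes over 2-fold higher, and 0 T cell, 0 plasmacytoid dendritic cell, 1 monocyte, 3 proliferation, 3 germinal centre and 8 apoptosis genes. Without x probe sets, 45 genes were over 2-fold higher, and 2 T cell, 2 neutrophil, 2 platelet, 0 plasmacytoid dendritic cell and 14 proliferation genes were detected. The cutoff was lower in that setting, with 9360 measured genes, so higher counts there do not come from the dropped probe sets alone. The 90th percentile cutoff gave 2 T cell, 2 neutrophil, 2 platelet and 1 erythroid gene, and the reference list without KRT10 gave 2 T cell, 2 neutrophil and 1 platelet gene. With either array alone, platelet detection ranged from 0 to 1. The counts of B cell lineage and immediate early genes stayed within 1.5 times under each alternative run. The ribosomal protein list came inside its random band under quantile normalization (0.046) and at the 99th percentile cutoff (0.231), where fewer and brighter genes form the random lists. Other lists went outside theirs. With no cutoff these were the naive B cell (0.165), MHC class II (0.148) and immediate early lists (0.116). The MHC class II list did so also at the 99th percentile cutoff (0.220), without x probe sets (0.168) and without KRT10 (0.169), and the naive B cell list without x probe sets (0.185). The median over probe sets put receptor signalling (0.108), quiescence (0.149), immediate early (0.127) and homing genes (0.109) outside, and quantile normalization B cell lineage (0.075). The other 178 of 192 list shifts stayed inside or outside the band as in the main setting, but some changed sign. Examples were plasma cell (0.052) and interferon response genes (0.111) with the median over probe sets, and homing genes (-0.101) at the 99th percentile cutoff. Other lists changed sign with smaller values, such as oxidative phosphorylation (-0.013) with the median over probe sets and apoptosis (-0.002) under quantile normalization. No centring and the signal floors left every percentile unchanged, so they were no separate check of the bands. The median over probe sets, which brings in probe sets below background, reversed MIDN (1.48), CARMIL1 (0.82), BBIP1 (0.38) and ATP13A3 (0.26). It moved 9 of the other named differences by more than the SD between arrays, 8 of them toward 0 and POLR2A away from it (-1.66). Where no reason is given, the cause was not tested. The correlation between probe sets of a gene was 0.272 at the 99th percentile cutoff and 0.045 under quantile normalization. Each was below the highest random pairing (0.323 and 0.056) but in the upper part of the range. No paired analysis was possible because only 1 group was analysed. Signal over background sets the limit of these arrays, since levels below the cutoff have no order.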

Other observations

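Further gene groups, chosen after seeing the data, add to the picture of the resting cells. Of 6 Toll-like receptor genes associated with B cells, 5 were above background on both arrays, namely TLR1, TLR7, TLR9, TLR10 (11.44 ± 0.05, SD, n = 2) and CD180 (11.08 ± 0.08), and none of the 5 Toll-like receptors associated with myeloid cells (TLR2, TLR3, TLR4, TLR5 and TLR8) was. Of 7 Fc receptor-like genes, 5 were above background, with FCRL2 at 13.38 ± 0.11 and FCRL3 at 13.32 ± 0.09, and FCRL4 and FCRLB were not. Among 16 cytokine genes, LTB (14.16 ± 0.12), IL16 (13.15 ± 0.05), TGFB1 (12.22 ± 0.60), IL6 (11.48 ± 0.08), TNF (10.73 ± 0.09), IL7 and IL12A were above background. IL10, IL2, IL4, IFNG and LTA were not well above it. In the TNF receptor family, 8 of 13 genes were above background, including CD40 (12.10 ± 0.07) and TNFRSF17 (11.13 ± 0.07). The other 5, among them TNFRSF4, TNFRSF8 and TNFRSF9, were not.

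Chosen only after the result was seen were the test within signal windows and both tests on immediate early genes. So were the interval for ribosomal members without an x and the repeat without the most extreme probe set. The limit of 0.2 log2 on matching gaps was also set then. The correlation between probe sets was planned, but the rule for reading it was set after the result was seen.

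Immediate early genes were above background in all 21 cases in cells labelled as resting. Cross-hybridisation of 1 probe set per gene is argued against for the genes with several probe sets, because 9 of 9 had at least 2 above background on both arrays. The other genes, such as FOS, JUNB, MYC and CD69, had 1 probe set each and could not be checked in this way. The median of the 36 T cell, NK cell and monocyte markers lay at -2.18 log2 relative to the cutoff on the array where it was higher. Of the 36, 5 were above background on both arrays. That pooled median could stay low with only 1 of these cell types present. Taken by list, medians on replicates 1 and 2 were 5.5 and 5.6 for T cells and 6.0 and 5.8 for NK cells. For monocytes they were 6.4 and 6.1, with 3 of 11 genes above background on both arrays. All lay below the cutoffs of 8.09 and 8.13, which argues against any of these cells as the main source of the immediate early signal. A response to purification or handling may also give such signal, and heat shock genes such as DNAJB1 and BAG3 were above background too. That hypothesis was not tested, as cells with another handling history are not analysed here, and no biological explanation was tested.

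Ribosomal protein genes were higher in replicate 2. A shift that depends on signal is consistent with the values within signal windows, where ribosomal minus other medians were -0.011 log2 between 14.5 and 15 (band -0.041 to 0.038), 0.001 above 15 and 0.025 from 14 to 14.5. The test written beforehand, against the 100 genes nearest in signal, put the list at the 100th percentile and by its own terms spoke against such a shift, but those genes were dimmer by a median of 0.445 log2, so they were no match. The shift was not confined to probe sets with an x, because the 40 members without one kept a median of 0.232. The 95% bootstrap interval of that median over members, 0.215 to 0.262, describes genes on these 2 arrays and not other samples. This interval could not decide what an x adds, since other genes of equal brightness were shifted as much. Some members without an x, such as RPS27 and RPL39, have probe sets with an s, which were not tested apart. The percentile of the 40 members among like lists (99.58) is set aside because, here too, the neighbours were dimmer, by 0.539. A shared change of translation transcripts is argued against by a list of translation factors and related non-ribosomal transcripts, such as TPT1 and NPM1. Its 16 measured genes lay at the 4.74th percentile (neighbours dimmer by 0.027), and at the 45.6th in binned matching. EIF5A, which was higher in replicate 2, is not in that list. No other biological explanation was tested.

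The 2 arrays differed little. Differences of 2 probe sets of the same gene correlated weakly, with a rho of 0.066 over 3631 genes. Noise of single probe sets could therefore account for most differences. The rho lay between the lowest and highest of 1000 random pairings (-0.034 to 0.078), but in the upper part of that range. Such a range is wider than the band used for lists, so a small shared part is not excluded. The 3 probe sets of EIF5A were all over 2-fold higher in replicate 2, but each carries an x or s. Different donors or antibody repertoires are consistent with the spread of 1 set. The 51 measured probe sets of antigen receptor segments and allele-dependent genes, taken only as a set, had an SD of 0.334, at the 99.15th percentile of matched sets. With the most extreme probe set left out of it and of each matched set, the SD was 0.298, at the 99.85th percentile, and whether the arrays came from different donors stays open, as the labels do not say.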
